A study of Mus musculus with 508 samples.

How the data were processed

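Messenger RNA was sequenced from 5 brain regions of mice of a Grin2a line (WT, Grin2a +/- and Grin2a -/-) and a Grin2b line (WT and Grin2b +/-) at 4 ages, 2, 4, 12 and 20 weeks. Per the labels' protocols the libraries were made with a stranded poly(A) kit. The deposited values are expected counts per gene, which the authors made with RSEM 1.3.0 against GRCm38.p6, per the submitters' processing notes, in 1 table for each of 508 libraries. The aligner and the annotation release are not given in the sources used here. RSEM shares reads that match several genes between them, so counts of near-identical copies are estimates. Of the expected counts 17.6% were not whole (tolerance 0.005), and all were rounded to whole numbers before testing. Each table lists the same 55401 genes by Ensembl identifier and symbol. For positions, identifiers were matched to the GENCODE M21 annotation of GRCm38, in which 55141 (99.5%) were found. A symbol shared by several identifiers, on 110 lines of the table, was kept apart by identifier.

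Groups follow the labels: line, region, age and genotype. For 1 library the title names the thalamus and the tissue label the striatum, and it was kept out of every comparison. Total counts per library ran from 9.47 M to 98.62 M with a median of 39.5 M. The mean fragment length of a library was taken from Gnai3, a gene with a single transcript in the tables, as its length less its effective length plus 1. All libraries had Y-linked and almost no Xist counts, so no term for sex was used. Libraries of a group were compared in pairs for repeated deposits. Over 13460 genes the smallest chi-square per gene among 1119 pairs was 4.97 (median 33.34), and 0 pairs lay under 3/2, so none was merged.

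The main test was the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) with TMM factors and robust dispersions. A fit was made for each line and region with a mean for each age and genotype, after filterByExpr (minimum count 10, minimum total count 15) by these groups, which kept 18810 to 20775 genes. From it came the difference from WT averaged over the 4 ages, the difference at each age, and the test that the difference varies between ages. A fit over all regions of a line (22843 genes in the Grin2a line, 21749 in the Grin2b line) gave the test that the difference varies between regions and the mean difference of the targeted gene over 20 comparisons. Adjusted p-values are Benjamini-Hochberg values within each fit and contrast, and a gene is called where one is under 0.05. Counts over regions or ages are sums of such calls. CPM were computed from the rounded expected counts, by library totals for single libraries and targeted genes and by TMM-scaled totals for mean levels of other genes over a region.

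Before the data were examined, 41 gene lists of pathways, cell types, regions and technical signs, the tests, the rule for named genes and the alternatives were fixed. Lists with at least 5 tested members were ranked against all other genes with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and again with an estimated one, and with fry, adjusted over lists and regions of a comparison. The targeted gene was left out of its lists. Counts of list members are given over all genes and adjusted over the list alone.

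Genes were named in the text by a fixed rule. It takes the 7 NMDA receptor subunits. In each region it takes the 2 highest and 2 lowest log2 differences among genes called on average over the ages, with the same sign at all 4 ages and a mean of at least 1 CPM. It adds up to 8 genes called with the same sign in at least 3 regions, up to 3 called members of each list that moved (or up to 2 members of a list that did not), and the 3 genes with the smallest p in the 3 region and age comparisons with the most calls. For differences between ages or regions it takes the 3 genes with the smallest p, and near the targeted gene up to 5. Predicted gene models are counted and not named. Values of 2 genes that the rule takes, and a map of the genes near Grin2a, are not reported here. Gm4202, Gm48273 and Sf3a2 fall outside it and were chosen after their values were seen, the first as a technical mark, the second as the start of a sequence search and the last as the single gene called in 1 alternative.

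The alternatives fixed then were limma-voom, DESeq2 1.42.0, RLE factors, no filter on low counts, a filter at a mean of 5 CPM, the replicate number as a block, a choroid plexus score as a covariate, each region and age comparison fitted alone, WT samples 1 to 5 or 6 to 10 alone in the groups of 10, the 20-week libraries of the Grin2a line left out, each replicate number left out in turn, and camera with an estimated correlation or fry for lists. After the data were seen 3 more were added: WT samples matched by technical marks (both WT sets of 5 stay in the fit as separate groups, so its counts differ from those with 1 set alone), 5 outlying libraries left out, and the 20-week libraries of the Grin2b line left out. A library was called outlying where the root mean square of its log2 deviations from its group's median exceeded 0.461. For Grin2a -/- against Grin2a +/- the matched version takes each genotype against its own matched WT samples and compares the differences.

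Genes within 10 Mb of the targeted gene were compared with all others by Fisher's exact test. Transcripts sharing at least 500 bp at 85% identity with Gm48273 were found with BLAST 2.17.0. For shared controls, counts of every library, WT included, were simulated 10 times from the WT mean of its age, without a genotype effect. For other splits of the samples, genotype labels were redrawn 99 times within age, a mouse number keeping its label over regions, and every count was made again with limma (trend, log2 CPM with a prior count of 2), for the real labels too. Those counts therefore differ from the edgeR counts. The real labels count as 1 of 100 splits. For library size, counts of each library of the Grin2a line were thinned binomially to the lowest total of its region and age, and the edgeR fit of each region was made again on the same genes.

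The fits were tested on simulated counts with the real means, library sizes and dispersions of SSC and 200 changed genes a line. For Grin2a -/- against WT, over 20356 genes, edgeR recovered 88% of genes changed by 0.5 on the log2 scale on average over ages and 100% of those changed by 1, with 10 false among 178 calls, and 0 calls in the unchanged Grin2a +/-. At 4 weeks alone it recovered 65.7% and 97%, and as a difference between ages 47.1% and 82.4%. For Grin2b +/- against WT, over 19317 genes, the same shares were 88% and 100% on average, 71.6% and 89.6% at 4 weeks, and 41.2% and 70.6% as a difference between ages. In that line, on average over ages in SSC, edgeR made 8 false calls among 185, DESeq2 28 among 211 and limma-voom 5 among 181. The test of differences between regions recovered 88% and 98% over 19536 genes. Simulated genes were drawn independently and without sets of libraries that differ, so these shares of false calls need not hold for the real libraries.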

Results

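The series measured messenger RNA by sequencing in 5 regions of the mouse brain, 2 of them cortical (prefrontal, here PFC, and somatosensory, SSC). The others were the thalamus (TH), the striatum (ST) and the hippocampus (HP). Mice were 2, 4, 12 or 20 weeks old. Grin2a and Grin2b encode the GluN2A and GluN2B subunits of the NMDA receptor, a glutamate-gated ion channel of excitatory synapses. The Grin2a line had 320 libraries, 129 from wild-type mice (WT), 97 labelled Grin2a +/- and 94 labelled Grin2a -/-. The Grin2b line had 187 libraries, 95 WT and 92 labelled Grin2b +/-. These 507 libraries formed 100 groups of region, age and genotype, and 72 of them held 5 libraries. A further 21 groups held 4, 1 group held 3, and 6 WT groups of the Grin2a line held 10. For 1 more library the title and the tissue label name different regions, so it entered no comparison. Total counts per library ranged from 9.47 M to 98.62 M with a median of 39.5 M, and 8 libraries had fewer than 15 M. Xist, the long RNA of the inactive X chromosome, reached at most 0.365 CPM, and the Y-linked Ddx3y was at least 23.5 CPM in every library. The labels do not say that the samples of a group came from separate mice, so the p-values measure the spread between these samples.

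The 6 WT groups of 10, in all 5 regions at 20 weeks and in PFC at 12 weeks, each split into samples 1 to 5 and samples 6 to 10 by technical marks. Gm4202, a predicted gene, was at 0 to 16.8 CPM in samples 1 to 5 and at 20.4 to 178.9 CPM in samples 6 to 10. Mean fragment length in PFC at 20 weeks was 220.9 bp ± 14.5 in WT samples 1 to 5 and 146.5 bp ± 21.8 in WT samples 6 to 10 (SD, n = 5 each). The labels name no batch. At 20 weeks the Grin2a +/- libraries carried the marks of WT samples 1 to 5 and the Grin2a -/- libraries those of samples 6 to 10, and in PFC at 12 weeks the reverse held. A comparison of one WT set of 5 with the other called between 2396 genes (PFC at 12 weeks) and 4255 genes (HP at 20 weeks) with edgeR. Values against the WT samples with the same marks, called marks-matched below, are therefore given beside those against all WT libraries. That choice was made after the data were seen. Counts with WT samples 1 to 5 or 6 to 10 alone come from fits without the other 5, so they differ from the marks-matched counts, whose fits keep both WT sets as separate groups.

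**Figure D1:**
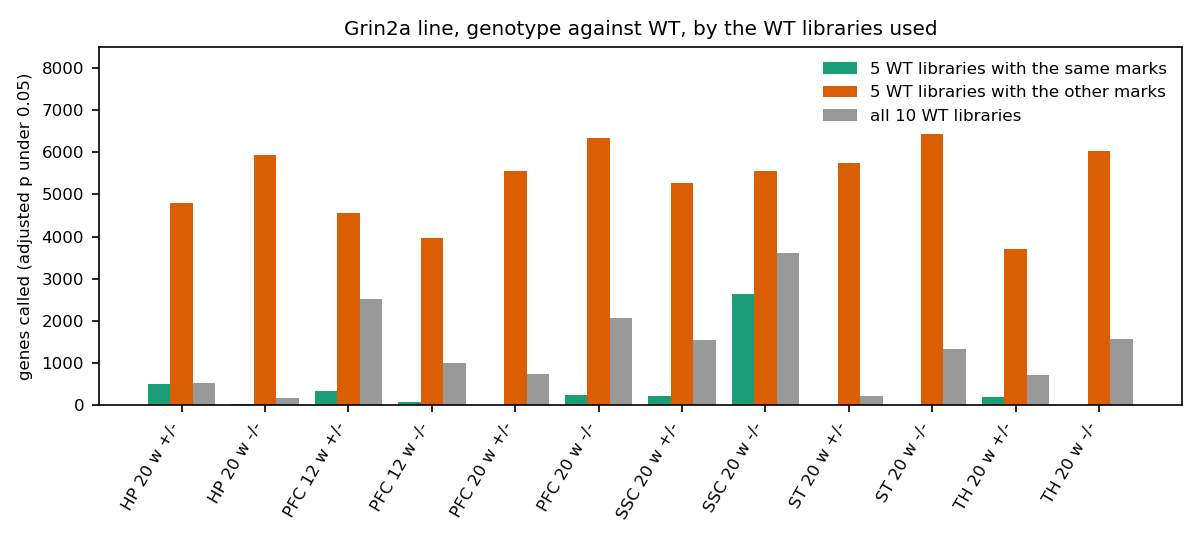
Number of genes called by edgeR at an adjusted p under 0.05 (vertical axis) for each Grin2a genotype in the 6 region and age groups with 10 WT libraries (horizontal axis, ages in weeks). Green bars are counts against the 5 WT libraries with the same technical marks, orange bars against the 5 with the other marks and grey bars against all 10; Grin2a -/- libraries of SSC at 20 weeks gave 2648, 5554 and 3611.

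Levels of the 2 targeted genes were compared first. Grin2a (ENSMUSG00000059003.12; chromosome 16, 9567898 to 9995560, GRCm38) fell by 1.52 ± 0.03 on the log2 scale (SE; mean over 20 region and age comparisons) in Grin2a -/- libraries, to 0.35 of WT. All 94 Grin2a -/- libraries lay below the WT median, and in 20 of 20 comparisons every one of them lay below every WT library, where 0.069 comparisons would do so by chance. Group means were still 24.2% to 42.9% of WT, so transcripts counted to the gene remained. In Grin2a +/- libraries Grin2a fell by 0.56 ± 0.028 to 0.68 of WT, with 97 of 97 libraries below the WT median. By region the mean over ages in Grin2a -/- ranged from -1.34 ± 0.08 in ST to -1.73 ± 0.056 in SSC, and in Grin2a +/- from -0.46 ± 0.08 in ST to -0.64 ± 0.054 in HP. WT group means ran from 66.8 CPM in TH to 382.4 CPM in HP.

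Grin2b (ENSMUSG00000030209.14; chromosome 6, 135713233 to 136173511, GRCm38) was not lower in the libraries labelled Grin2b +/-. Its mean log2 difference over the 20 comparisons was 0.09 ± 0.041 (edgeR unadjusted p = 0.0236), 33 of 92 libraries lay below the WT median, and group means ran from 83.3% to 145.5% of WT. With sample number 1 left out it was 0.06 ± 0.046 (p = 0.231) and with number 2 left out 0.09 ± 0.049 (p = 0.0688). It was lower in 5 of 20 comparisons and was called in 0 of them, and in none did every library lie below WT. The files do not show whether counted reads include a disrupted transcript, so the genotype rests on the labels alone. Directions below refer to libraries labelled Grin2b +/-. None of the other NMDA receptor subunits (Grin1, Grin2c, Grin2d, Grin3a and Grin3b) passed the threshold on average over the ages in any region of the 3 comparisons with WT, and neither did Grin2b in the Grin2a line. The nearest was Grin2d, 0.17 ± 0.056 in PFC of Grin2a +/- (edgeR adjusted p = 0.0732). Adjusted over the list alone, without the targeted gene, the subunits gave 1 higher and 3 lower calls over the 5 regions in Grin2a -/-. In Grin2a +/- they gave 1 higher and 1 lower, and in Grin2b +/- 0 of either.

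**Figure D2:**
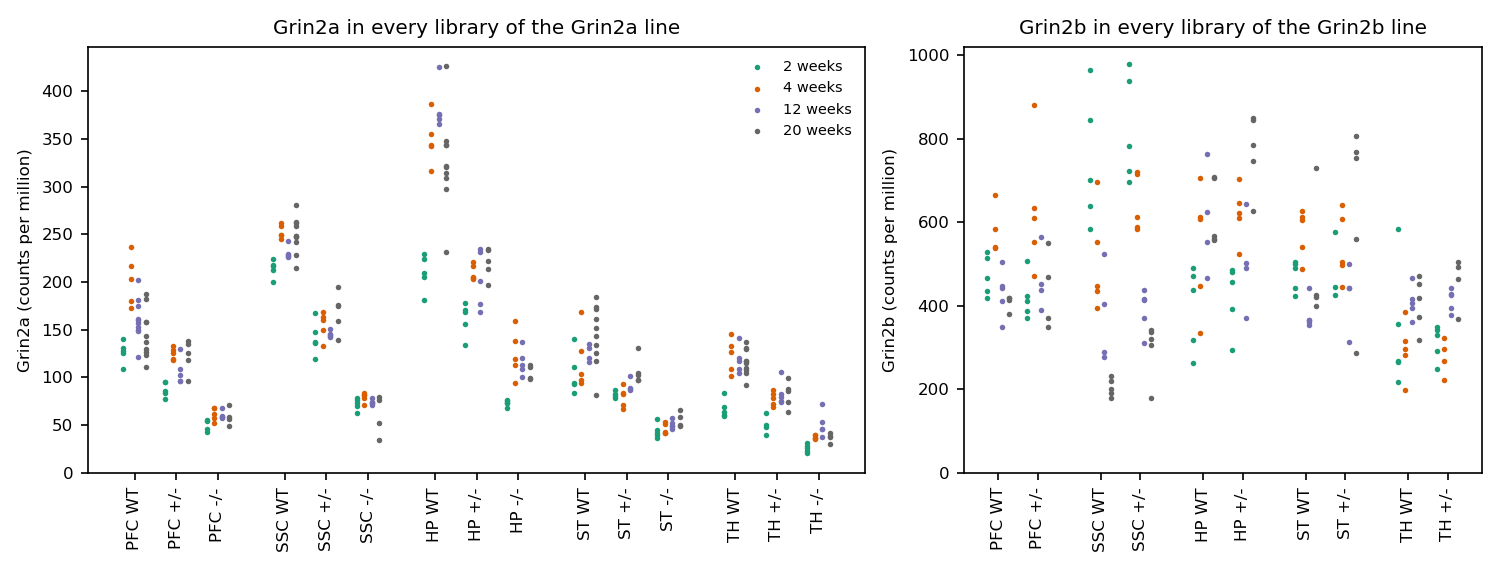
CPM (vertical axes) of Grin2a in every library of the Grin2a line, left, and of Grin2b in every library of the Grin2b line, right, by region and genotype (horizontal axes); each point is a library, colored by age in weeks. Grin2a group means of Grin2a -/- lie at 24.2% to 42.9% of WT, and Grin2b group means of libraries labelled Grin2b +/- at 83.3% to 145.5% of WT.

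The next comparison asked which genes differ when both copies of Grin2a are targeted, on average over the 4 ages. In Grin2a -/- libraries, genes of neuropeptides and peptide-binding proteins of inhibitory neurons rose in the cortex and hippocampus. Cort (cortistatin, ENSMUSG00000028971.4) rose by 1.48 ± 0.136 in HP (SE; edgeR adjusted p = 4.85e-12; 19 of 19 libraries above the WT median), by 0.95 ± 0.127 in SSC and by 0.77 ± 0.113 in PFC. Npy (neuropeptide Y, ENSMUSG00000029819.6) rose by 0.86 ± 0.064 in HP, 0.52 ± 0.057 in SSC and 0.37 ± 0.072 in PFC. Crhbp, a secreted protein that binds corticotropin-releasing hormone, rose by 0.90 ± 0.111, 0.76 ± 0.05 and 0.57 ± 0.058 in the same regions. Sst (somatostatin) rose by 0.60 ± 0.057 in SSC (adjusted p = 1.22e-11; 18 of 19 libraries). In HP, Gad1 and Gad2, which make GABA, rose by 0.28 ± 0.049 and 0.23 ± 0.061, and Gad2 lost its call with any 1 of the 5 sample numbers left out (0.22 to 0.26). In ST, Npy differed by 0.13 ± 0.076 (adjusted p = 0.49) and Crhbp by 0.54 ± 0.192 (adjusted p = 0.254).

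Of 23 listed interneuron genes, 4 rose in PFC, 4 in SSC and 7 in HP, none fell, and 0 passed in ST and TH. Summed over regions that is 15 higher and 0 lower calls, or 19 higher and 1 lower when adjusted over the list alone. The list as a whole ranked above other genes in HP (median log2 difference 0.12; camera adjusted p = 4.2e-19, and adjusted p = 2.5e-05 with an estimated correlation). It also passed with the preset correlation in SSC and PFC, where the adjusted p was 0.075 and 0.74 with an estimated correlation. In PFC the median of the list was -0.005. Against marks-matched WT the 9 pairs of Npy, Cort and Crhbp with PFC, SSC and HP stayed past the threshold, with Cort at 0.67, 0.96 and 1.50 in turn.

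**Figure D3:**
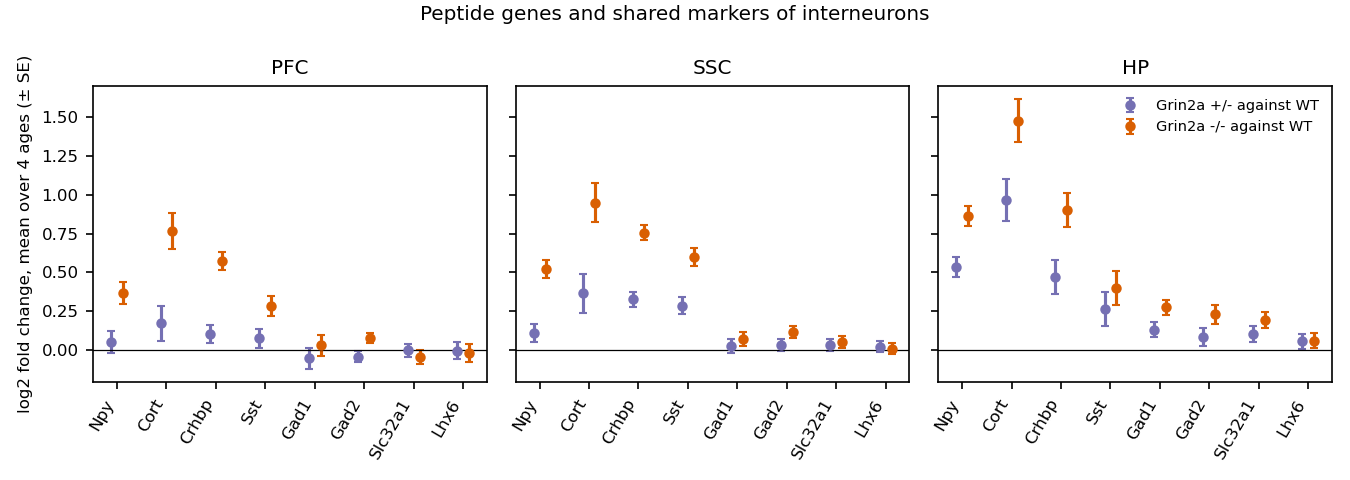
Log2 difference from all WT libraries, mean over 4 ages (vertical axis), of 4 peptide genes and 4 shared interneuron markers (horizontal axis) in PFC, SSC and HP; points are edgeR estimates for Grin2a +/- (purple) and Grin2a -/- (orange) and bars are 1 standard error each way. Cort in HP lies at 1.48 ± 0.136 in Grin2a -/- and at 0.96 ± 0.135 in Grin2a +/-.

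Some genes induced by neuronal activity were higher as well. Of 28 delayed activity-regulated genes, 7 rose in PFC, 9 in SSC, 6 in HP and 1 in ST, while Cartpt fell in SSC and 1 gene fell in HP (23 higher and 2 lower calls, or 45 higher and 5 lower adjusted over the list alone). Nptx2, a secreted protein that clusters AMPA receptors, rose by 0.62 ± 0.077 in SSC, 0.40 ± 0.077 in PFC and 0.40 ± 0.089 in ST. Bdnf, a neurotrophin, rose by 0.42 ± 0.08 in PFC, and Ptgs2 (cyclooxygenase-2) by 0.52 ± 0.081 there. Scg2, a granin from which secretoneurin is made, rose by 0.37 ± 0.046 in SSC and 0.33 ± 0.057 in HP. In HP, Vgf and Crh (corticotropin-releasing hormone) rose by 0.28 ± 0.054 and 0.70 ± 0.136. The list median was positive in 5 of 5 regions (0.08 to 0.16), and camera passed in all 5. The smallest adjusted p was 0.17 with an estimated correlation, so the move of the list beyond other genes rests on the preset correlation. Nptx2 was not called in PFC without sample number 3 (0.39) nor in ST without number 2, 3, 4 or 5 (0.34 to 0.39), and Crh was not without number 5 (0.62).

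Immediate early genes, transcribed within minutes of stimulation, gave 9 higher and 0 lower calls over the 5 regions for the 28 listed (26 and 0 adjusted over the list alone). Npas4 rose by 0.66 ± 0.16 in PFC and 0.83 ± 0.194 in SSC, Gadd45b by 0.38 ± 0.068 in SSC, and Fos by 0.55 ± 0.102 in HP (18 of 19 libraries above the WT median). Camera called the list up in 4 regions (median 0.20 in HP; smallest adjusted p = 0.16 with an estimated correlation). At the same time the glucocorticoid response list, fixed as a sign of handling stress, ranked lower in 4 regions (medians -0.19 to -0.11; adjusted p at least 0.74 with an estimated correlation), with 0 genes called by edgeR over all genes and 5 lower calls over the 5 regions adjusted over the list alone. The circadian clock output list ranked lower in 3 regions (adjusted p at least 0.23 with an estimated correlation). Over the 5 regions it gave 1 higher and 3 lower calls, or 1 and 15 adjusted over the list alone. Hlf, a clock-controlled transcription factor, fell by 0.33 ± 0.042 in SSC and by 0.21 ± 0.039 in PFC. Npas4 was not called in PFC without sample number 2, 3, 4 or 5 (0.59 to 0.66) nor in SSC without number 2 (0.84) or 5 (0.72). Fos in HP was not without number 5 (0.48), and Hlf in PFC was not without number 3 (-0.18).

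In SSC of Grin2a -/- mice, markers of excitatory neurons moved apart. Cartpt, a neuropeptide precursor, fell by 1.10 ± 0.11 (adjusted p = 9.97e-11; 18 of 19 libraries below the WT median). Rorb, a transcription factor of layer 4, fell by 0.38 ± 0.072, Pcdh8, a protocadherin, by 0.55 ± 0.077, Fibcd1 by 0.40 ± 0.079 and Calb1 (calbindin) by 0.31 ± 0.069. Myl4, a myosin light chain, rose by 0.60 ± 0.11, and Colq, the collagen tail of acetylcholinesterase, by 0.95 ± 0.18 from a WT mean of 0.961 CPM. Of 19 listed cortical excitatory genes, 1 rose and 4 fell in SSC (camera down; adjusted p = 0.4 with an estimated correlation), and of 19 hippocampal excitatory genes 0 rose and 3 fell there (adjusted p = 0.075 with an estimated correlation). Immature neuron genes Marcksl1, Neurod1 and Mex3a fell by 0.26 ± 0.054, 0.35 ± 0.077 and 0.29 ± 0.07. Of the postsynaptic density list, Lrrtm1, Homer2 and Nlgn3 fell in SSC by 0.17 ± 0.041, 0.22 ± 0.062 and 0.10 ± 0.03, and none of 33 rose in any region. Adjusted over the list alone there were 4 higher and 4 lower calls over the 5 regions (camera up in 1 region and down in 2, smallest adjusted p = 0.48 with an estimated correlation). With sample number 5 left out Calb1 (-0.24), Neurod1 (-0.29), Mex3a (-0.25), Lrrtm1 (-0.15), Homer2 (-0.21) and Nlgn3 (-0.09) were not called in SSC.

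Several gene groups showed small shifts across the other lists. Nuclear-encoded oxidative phosphorylation genes ranked higher in SSC (median 0.08, 74 of 76 genes positive) and lower in TH (median -0.09, 1 of 76 positive), with 1 gene, Sdha in SSC, called over all genes; the smallest adjusted p was 0.7 with an estimated correlation. Ebp, an enzyme of cholesterol synthesis, rose in SSC by 0.17 ± 0.039 and was not called without sample number 5 (0.16). Among glial and vascular lists, endothelial genes in HP had a median of 0.23 (0 called over all genes, 14 of 18 higher adjusted over the list alone; adjusted p = 0.16 with an estimated correlation) and astrocyte genes in HP one of 0.11 (0 called, 8 of 22 higher adjusted over the list alone; 0.2 with an estimated correlation). Myelin genes had a median of 0.16 in SSC and -0.19 in TH with 0 called in either (0.74 with an estimated correlation).

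Counts by region follow from the same fits. In Grin2a -/- against all WT, edgeR called 264 genes in PFC, 565 in SSC, 199 in HP, 21 in ST and 17 in TH, 1066 in all (499 higher, 567 lower). Against marks-matched WT it called 102, 508, 186, 13 and 14, 823 in all (474 higher, 349 lower), and 632 were called with the same sign both ways. Nlgn3 and Sdha in SSC, Nptx2 in ST, Bdnf in HP and Scg2 in PFC were called against all WT only. Limma-voom called 1004 and DESeq2 1704. With sample number 1, 2, 3, 4 or 5 left out, 584, 575, 569, 1031 and 404 genes were called in turn. At single ages 10430 calls were made over 20 comparisons, 61 at 2 weeks, 299 at 4 weeks, 1329 at 12 weeks and 8741 at 20 weeks, and 3104 to 6784 in all without 1 sample number. Against marks-matched WT these were 70, 465, 434 and 2920, of which 2638 were in SSC at 20 weeks. There Crhbp rose by 1.01 ± 0.09 and Scg2 by 0.83 ± 0.085, in 4 of 4 libraries each, and Ccnd2, a cyclin, differed by -0.78 ± 0.098.

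Effects that differ between ages or regions were tested as such. The age difference was called for 1753 genes over the 5 regions in Grin2a -/-, and for 167 against marks-matched WT, 1137 without the 20-week libraries and 83 to 1407 without 1 sample number. Ccnd2 in SSC (adjusted p = 0.00124) and Rhobtb2 in PFC (adjusted p = 0.00496; -0.35 ± 0.042 at 20 weeks and 0.03 ± 0.047 at 2 weeks) were among the genes with the smallest p. The region difference was called for 320 genes (214 against marks-matched WT, 872 without the 20-week libraries and 25 to 547 without 1 sample number). Libraries with 1 number deviated together between regions (mean r 0.214), which this test does not take into account, and a limma-voom fit with a replicate block over regions called 746. Dcbld2 fell by 0.37 ± 0.048 in SSC and differed by at most 0.10 elsewhere (adjusted p of the difference 1e-06). Ddn (dendrin, a postsynaptic protein) differed by 1.34 ± 0.378 in TH and by -0.13 to 0.05 in the other regions (adjusted p of the difference 1.5e-05). Adjusted p of region differences come from the fit over all regions, with a shared spread, and SE from the fit of each region. Such a p therefore does not measure a spread that is larger in 1 region. In TH the cortical and hippocampal excitatory lists had medians of 0.32 and 0.34.

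Genes around Grin2a on chromosome 16 and a set of repeat-derived transcripts were called in most regions. Clec16a (chromosome 16, 10545339 to 10744878), an endolysosomal protein, rose by 0.45 to 0.56 in all 5 regions (SE 0.03 to 0.063), with 18 of 18 libraries above the WT median in PFC and 19 of 19 in each other region. Emp2, a membrane protein, fell in 5 regions by 0.33 to 0.94, and Tekt5 (tektin 5) by 1.21 ± 0.099 in PFC and 0.44 ± 0.072 in ST. Within 10 Mb of Grin2a 4 of 184 genes were called in ST (2.2%) against 16 of 19975 elsewhere (0.08%; Fisher's exact p = 2.9e-05, two-sided), and in TH 3 of 183 against 13 of 20234 (p = 0.00036). Olfr624 and Olfr1330, annotated olfactory receptors on chromosomes 7 and 4, fell by 0.71 to 1.37 and by at least 0.86 in the 5 regions. The transcript of Olfr624 shares 987 bp at 94.6% identity with the predicted gene Gm48273, which 46 genes matched over at least 500 bp at 85% identity or more. Counting could divide reads between such copies, so the values of Olfr624 are uncertain. Olfr1330 was not among the matching genes tested. Without sample number 5 Emp2 in TH (-0.51) and Olfr1330 in HP (-0.82) were not called.

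The Grin2a +/- comparison asked what follows when 1 copy is targeted. Hippocampal peptide genes were among the highest: Cort rose by 0.96 ± 0.135 in HP (edgeR adjusted p = 8.44e-06), Npy by 0.53 ± 0.064 (adjusted p = 1.11e-07) and Crhbp by 0.47 ± 0.11, with 19, 19 and 18 of 20 libraries above the WT median, and Crhbp rose by 0.33 ± 0.05 in SSC. Crhbp in HP lost its call without sample number 1, 3, 4 or 5 (0.38 to 0.52). Clec16a rose by 0.24 to 0.32 in PFC, SSC, HP and ST and differed by 0.23 ± 0.063 in TH (adjusted p = 0.346), and Olfr624 fell by 0.27 to 0.56 in 5 regions, but in PFC it was not called against marks-matched WT (-0.24; adjusted p = 0.106). In SSC, Abi3bp and Ccdc80, extracellular matrix proteins, rose by 0.36 ± 0.085 and 0.35 ± 0.075, while Hlf and Bhlhe40 of the clock list fell by 0.23 ± 0.041 and 0.40 ± 0.095, and Pcdh8 fell by 0.31 ± 0.075. Without sample number 2 none of Abi3bp (0.30), Ccdc80 (0.37), Bhlhe40 (-0.41) and Pcdh8 (-0.26) was called. Muc3a and Lrrc29 stood highest in PFC (0.57 ± 0.131 and 0.53 ± 0.103).

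In PFC of Grin2a +/-, a minority of the genes on 3 protein quality control lists was called, all lower. Proteasome subunits gave 0 higher and 7 lower of 31 (14 lower adjusted over the list alone), such as Psmc2 at -0.12 ± 0.029, and the median of the 31 was -0.07. Unfolded protein response genes gave 0 higher and 4 lower of 22 (Dnajc3 -0.15 ± 0.039, Pdia3 -0.15 ± 0.04), and chaperones 3 lower of 17 (Dnaja1 -0.12 ± 0.029). Adjusted p was 0.61, 0.53 and 0.53 with an estimated correlation. Against marks-matched WT 1 proteasome gene, 0 unfolded protein response genes and 1 chaperone were called: Psmc2 and Dnaja1 stayed called (-0.11 each) and Dnajc3 and Pdia3 did not (-0.14 and -0.09). Without sample number 2 none of Psmc2 (-0.13), Dnaja1 (-0.10), Dnajc3 (-0.13), Pdia3 (-0.14) and Errfi1 (-0.16) was called. The glucocorticoid response list ranked lower in 5 of 5 regions (medians -0.26 to -0.12; 1 gene lower, Errfi1 in PFC at -0.16 ± 0.039, and 8 lower calls over the regions adjusted over the list alone; smallest adjusted p = 0.53 with an estimated correlation). In ST astrocyte genes had a median of -0.13 (0 called, 10 of 22 lower adjusted over the list alone; 0.53 with an estimated correlation). In TH striatal, cortical and hippocampal neuron markers had medians of 0.47, 0.40 and 0.27, and choroid plexus genes 0.57, with 0 called in each.

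Counts for Grin2a +/- were 909 genes in PFC, 77 in SSC, 42 in HP, 6 in ST and 4 in TH, 1038 in all (593 higher, 445 lower). Against marks-matched WT they were 323, 120, 41, 9 and 9, 502 in all (241 higher, 261 lower), and 348 were shared with the same sign. Those called against all WT only included Homer1, Plk2, Hspd1, Psma2 and Psmb1 in PFC, Herc1 in HP and Hmgcs1 and Nr3c2 in SSC, and those called against marks-matched WT only included Crhbp in PFC. Limma-voom called 976 and DESeq2 1588. With sample number 1, 2, 3, 4 or 5 left out 804, 111, 366, 635 and 203 genes were called in turn, and 2546 without the 20-week libraries. Single ages gave 6435 calls (2602 to 6112 without 1 sample number) and 1731 against marks-matched WT, with 18, 42, 2626 and 3749 at 2, 4, 12 and 20 weeks against 26, 133, 857 and 715. In SSC at 20 weeks Ccnd2 fell by 0.68 ± 0.089 in 5 of 5 libraries. The age difference was called for 982 genes (363 matched, 244 without the 20-week libraries and 2 to 786 without 1 sample number), among them Dync1h1 (dynein heavy chain) in HP, at -0.48 ± 0.081 at 4 weeks and 0.09 ± 0.07 at 20 weeks (adjusted p = 0.00114). The region difference was called for 310 genes (391 matched, 381 with a replicate block over regions, 1589 without the 20-week libraries, 160 without 5 outlying libraries and 0 to 534 without 1 sample number). Among them Ddn was at 1.50 ± 0.378 in TH and -0.22 to 0.08 elsewhere (adjusted p of the difference 2.66e-07, from a spread shared by all regions).

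Grin2a -/- and Grin2a +/- were also compared directly. Over the ages 2560 genes were called (1345 higher, 1215 lower in Grin2a -/-), 2347 of them in PFC, and 1403, 1351, 970, 1905 and 1593 without sample number 1 to 5 in turn. After each genotype was first set against its marks-matched WT samples, 120 were called (85 higher, 35 lower), 87 of them in PFC and 5, 3 and 5 in HP, ST and TH. Both genotypes share their WT libraries in the all-WT fits, which ties their values by chance alone. The correlation of their log2 differences across genes was 0.374 in PFC, 0.395 in SSC, 0.434 in HP, 0.392 in ST and 0.524 in TH, against 0.415, 0.468, 0.462, 0.475 and 0.448 for simulated unchanged groups. Covariances were 0.00986, 0.00993, 0.0102, 0.00976 and 0.0184 against simulated 0.00687, 0.00747, 0.00844, 0.00926 and 0.0107. Against marks-matched WT, which the genotypes share in part, the correlations were 0.377, 0.462, 0.5, 0.518 and 0.628 against simulated 0.244, 0.379, 0.374, 0.394 and 0.357, and the covariances 0.00989, 0.0111, 0.0112, 0.0118 and 0.0208 against 0.00459, 0.00644, 0.00726, 0.00813 and 0.00909. With odd and even WT libraries given to different genotypes the correlation was 0.074 and 0.123 in PFC, 0.05 and 0.093 in SSC, 0.184 and 0 in HP, 0.108 and 0.06 in ST, and 0.306 and 0.135 in TH. In HP limma called 9 genes higher in both against 0.05 for independent lists and 7 lower in both against 0.1, and with WT libraries divided 4 and 3 higher and 5 and 2 lower. Genes are not independent replicates in these correlations. The simulations drew genes independently and gave all libraries of an age the same WT mean. They left out the WT sets that differ by technical marks, so they do not show what unchanged libraries with such sets would give.

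The Grin2b line addresses 1 targeted copy of Grin2b. On average over the ages genes passed the threshold in SSC alone: 96 genes, 75 higher and 21 lower. Cartpt stood highest (0.43 ± 0.1; edgeR adjusted p = 0.0389; 16 of 20 libraries above the WT median), beside Nes (nestin, 0.43 ± 0.1). Ldb2, a LIM-domain cofactor, and Inf2, a formin, stood lowest (-0.39 ± 0.09 and -0.27 ± 0.051). Of 18 endothelial genes 5 were called higher in SSC, such as Flt1 (a VEGF receptor, 0.42 ± 0.093), Ptprb (0.37 ± 0.077) and Esam (0.17 ± 0.033). In SSC at 20 weeks these libraries and WT did not overlap in mean fragment length (169.6 to 175.1 bp against 158.5 to 163 bp) or total counts (35.5 M to 60.5 M against 21.9 M to 32.3 M), and mitochondrially encoded transcripts took 10.4% ± 2.11 against 16.1% ± 2.18 (SD, n = 5 each). Without the 20-week libraries, left out after the data were seen, 1 gene was called over the 5 regions in place of 96, Sf3a2 in ST (-0.25 ± 0.042), and Flt1, Ptprb and Esam in SSC were at 0.22, 0.21 and 0.08. In PFC, HP, ST and TH edgeR called 0 genes, with 1069, 1899, 1479 and 1473 at an unadjusted p under 0.05. Limma-voom called 0 in each and DESeq2 12, 9, 9 and 139. Limma-voom called 63 in SSC and DESeq2 322. The total of 96 became 2, 7, 6, 41 and 737 with sample number 1, 2, 3, 4 or 5 left out, and without number 1 none of Cartpt (0.36), Nes (0.40), Ldb2 (-0.31), Inf2 (-0.27), Flt1 (0.41), Ptprb (0.37) and Esam (0.16) was called. The test of differences between regions called 6 genes (22 without the 20-week libraries, 0 to 17 without 1 sample number). Among them Nrn1 (neuritin) differed by 1.18 ± 0.378 in ST and by -0.19 to 0.04 elsewhere (adjusted p of the difference 0.00779, from a spread shared by all regions).

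Vascular and immune lists ranked above other genes in several regions of these libraries with the preset correlation. The endothelial list was up in 5 of 5 regions (medians 0.11 to 0.36; 5 higher calls over all genes and 61 adjusted over the list alone, summed over regions), with adjusted p = 0.029 in TH and at least 0.084 elsewhere with an estimated correlation. In TH mural cell genes (median 0.26), mitochondrially encoded genes (0.23) and reactive astrocyte genes (0.23) also passed, at adjusted p = 0.029, 0.035 and 0.035 with an estimated correlation. In TH at 4 weeks mitochondrially encoded transcripts took 6.12% to 6.8% of counts against 3.42% to 6.06% in WT. The interferon and MHC class I list was up in 5 regions (medians 0.09 to 0.20; smallest adjusted p = 0.13 with an estimated correlation), and Lgals3bp rose by 0.16 ± 0.036 in SSC. Choroid plexus genes had medians of 0.69 in TH and 0.52 in HP and meningeal fibroblast genes one of 0.51 in TH, with 0 called over all genes in these. With a choroid plexus score as a covariate, 40 genes were called over the 5 regions in place of 96. Thalamic neuron markers had a median of -0.55 in HP, where 1 WT library at 2 weeks carried thalamic transcripts. In TH, where the lists above passed, 1 WT library at 2 weeks had hippocampal markers at a mean of 5.45 log2 CPM against 3.29 in the other WT samples.

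At single ages 3603 calls were made, 1947 in SSC at 20 weeks, 824 in TH at 4 weeks, 430 in ST at 4 weeks and 373 in HP at 4 weeks, with at most 9 in any other comparison. Fragment length and total counts differed without overlap between genotypes in SSC at 20 weeks, as did the mitochondrial share in TH at 4 weeks. Over the 20 comparisons of the Grin2b line fragment length did not overlap in 2. Total counts, the mitochondrial share and the choroid plexus score did not overlap in 1 each. Without the 20-week libraries there were 1732 calls, without 5 outlying libraries 5990, and with 1 sample number left out between 382 (number 3) and 8366 (number 5). In SSC at 20 weeks Arl6ip5 and Dnajb1, a co-chaperone, rose by 0.39 ± 0.052 and 0.49 ± 0.069 and Ube2r2, a ubiquitin-conjugating enzyme, fell by 0.31 ± 0.041, in 5 of 5 libraries each. In TH at 4 weeks H2-D1, an MHC class I gene, rose by 0.65 ± 0.093 in 4 of 4 and was not called without number 1 (0.65). The age difference was called for 336 genes, 232 in TH and 103 in SSC (1 without the 20-week libraries, 1217 without 5 outlying libraries, 1 to 3861 without 1 sample number), such as Tdrp in SSC (0.53 ± 0.079 at 20 weeks and -0.25 ± 0.08 at 12 weeks; adjusted p = 0.00573). Within 10 Mb of Grin2b 2 of 147 genes were called in SSC (Cmas -0.10 ± 0.02, Itpr2 0.18 ± 0.043) against 94 of 19395 elsewhere (Fisher's exact p = 0.16). Over genes, the mean differences of Grin2b +/- correlated with those of Grin2a -/- at r from -0.152 in SSC to 0.217 in HP, with no shared libraries.

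**Figure D4:**
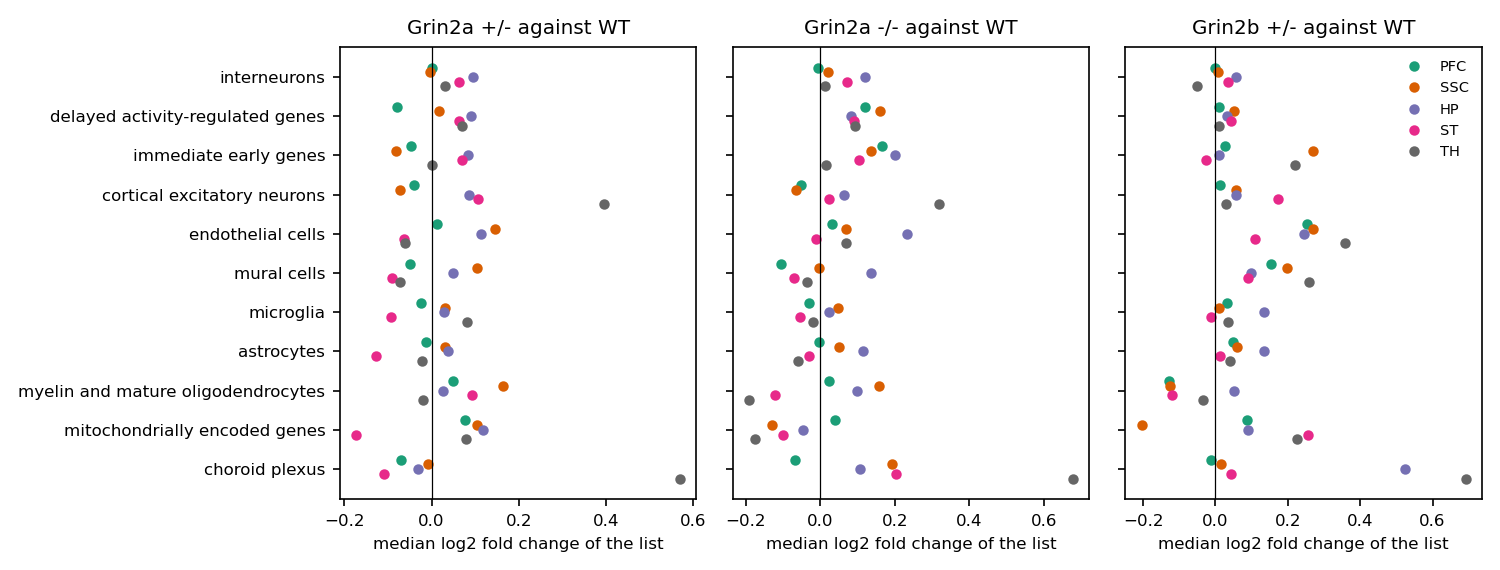
Median log2 difference from WT over the genes of 11 lists (horizontal axis, log2; lists on the vertical axis), mean over 4 ages, in a panel for each comparison with WT; each point is a region, colored by region. The delayed activity-regulated list is positive in all 5 regions of Grin2a -/- (0.08 to 0.16) and the endothelial list in all 5 regions of libraries labelled Grin2b +/- (0.11 to 0.36).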

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

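The test of library batch for the calls of the Grin2a line, all tests of the peptide genes, and the tests of adjacent genes and of reads shared between repeat copies were chosen after the results were seen.

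The Grin2a line had most of its calls at 20 weeks and in PFC at 12 weeks. In fits that keep 1 of the 2 WT sets of 5, 4258 genes were called over these 12 comparisons against the set with the same technical marks and 63936 against the other, while all 10 WT libraries gave 16013, so a library batch is a likely cause of most of them. Library size is argued against as the whole cause, since 12572 of the 16013 calls stayed called with the same sign when every library of a region and age was thinned to 1 total count. Loss of Grin2a stays open as a cause of the remaining calls: 5 of 100 splits of the Grin2a -/- and marks-matched WT libraries, the real labels counted among the 5, gave as many calls at single ages.

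Npy, Cort and Crhbp were higher in Grin2a -/- libraries of PFC, SSC and HP. The library sets seen in the split WT groups are argued against as the whole cause, since all 9 pairs stayed called against marks-matched WT. That fit changes the WT libraries only in those groups, and the genes were picked for being called. A library batch in the other groups was therefore not tested. More interneurons in the tissue would raise the shared markers Gad1, Gad2, Slc32a1 and Lhx6 as much, and the peptide genes rose beyond these by 0.486 ± 0.075 in PFC, 0.672 ± 0.08 in SSC and 0.905 ± 0.104 in HP (log2, SE). The peptide genes were picked from these data for their rise, and Sst was left out of the score, so this excess may be overstated. Against marks-matched WT, Grin2a +/- lay between WT and Grin2a -/- in 9 of 9 pairs and was called in 5 of 9. Outside the split WT groups both genotypes share their WT libraries, and the genes were picked for a high Grin2a -/-. The pairs are also not independent, since libraries with the same number deviated together between regions. How often this order arises without an effect was not tested, so the order alone does not show an effect of copy number. A candidate explanation is that loss of Grin2a copies raises these transcripts within peptide-expressing interneurons, while a larger share of that subtype was not tested and more interneurons stay open as a part of the change, since the shared markers themselves rose by 0.171 ± 0.038 in HP and 0.069 ± 0.031 in SSC.

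Genes near Grin2a and copies of 1 repeat were called in several regions of the Grin2a line. Of 132 other windows of 20 Mb, 0 had as high a share of genes called in ST or TH as the window around Grin2a (2.09% in Grin2a -/-, highest other 1.19%), while over any region 1 was as high (8.9%, highest other 11.21%). A strain segment carried with the targeted allele may account for these calls. An effect of the targeted locus on adjacent genes alone stays open: 3 of the 4 genes called in ST or TH within 10 Mb lay within 1 Mb, and over any region 5 of 17 did, where calls elsewhere in the genome are more frequent. For the copies of the repeat, reads shared between copies may account for them. In Grin2a -/- against marks-matched WT 5 to 7 of the 43 or 44 matching genes a region were called lower. That was more often than other genes in 5 of 5 regions (Fisher's exact p at most 2.3e-06). Most were not called lower, and in PFC 20 of 44 were negative (median 0.022). Fisher's test treats the genes as independent, which copies that share reads are not, so its p-values may be too small. The search also began from a gene, itself left out of the counts, that was picked for its small p in Grin2a -/-.

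Several libraries stood apart in the CPM of the targeted gene relative to the range of their group. The measure was the gap to the nearest other library divided by that range, and it picked out 1 library in each of several groups. For Grin2a these were WT sample 2 of HP at 12 weeks (0.811), Grin2a -/- sample 3 of PFC at 12 weeks (0.801) and WT sample 1 of SSC at 12 weeks (0.841). Among Grin2a +/- libraries they were sample 1 of ST at 12 weeks (0.865), sample 5 of ST at 20 weeks (0.768) and sample 3 of TH at 12 weeks (0.733). For Grin2b they were WT sample 4 of PFC at 20 weeks (0.848), sample 5 labelled Grin2b +/- of SSC at 20 weeks (0.791), WT sample 3 of ST at 12 weeks (0.855) and WT sample 4 of ST at 20 weeks (0.917). These are 10 of 99 groups, and chance picks out about 1 in 20 groups, or 5. In a tight group the distance in CPM can be small: WT sample 1 of SSC at 12 weeks had 242.7 CPM of Grin2a against 226.6 to 229.1 in the others.

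Differences between ages picked out the next genes, each with the edgeR adjusted p of the difference. In HP of Grin2a +/- these were Dync1h1 (0.00114), Ifnar2, an interferon receptor subunit (0.00117; 0.41 ± 0.07 at 12 weeks and -0.19 ± 0.068 at 2 weeks), and Ubr4, a ubiquitin ligase (0.00161; -0.51 ± 0.078 at 12 weeks and 0.12 ± 0.077 at 2 weeks). In Grin2a -/- they were Rnf113a2 (0.00124; 0.56 ± 0.077 at 20 weeks, -0.10 to -0.04 before) and Ccnd2 (0.00124) in SSC and Rhobtb2 (0.00496) in PFC. In libraries labelled Grin2b +/- they were Tdrp (0.00573) and Dnajb1 (0.00573; 0.49 ± 0.069 at 20 weeks and -0.12 ± 0.071 at 12 weeks) in SSC and Rprd1b (0.00713; 0.23 ± 0.041 at 20 weeks and -0.16 ± 0.039 at 4 weeks) in PFC. Over all genes and regions the age test called 982 genes in Grin2a +/-, 1753 in Grin2a -/- and 336 in Grin2b +/-.

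Differences between regions picked out a further set of genes, with adjusted p from a spread shared by all regions. In Grin2a +/- these were Ddn (2.66e-07), Spag6l (2.24e-06; 0.80 ± 0.168 in TH, -0.06 to 0.07 elsewhere) and Rin1, a Ras effector of forebrain neurons (2.24e-06; 1.25 ± 0.336 in TH). In Grin2a -/- they were Tekt5 (8.68e-08), Dcbld2 (1e-06) and Ddn (1.5e-05). In Grin2b +/- they were Nrn1 (0.00779), Arsj, an arylsulfatase (0.0353; -0.71 ± 0.192 in HP and 0.74 ± 0.309 in ST), and Ube2r2 (0.0428; -0.10 ± 0.021 in SSC and 0.07 ± 0.026 in TH). The region test called 310, 320 and 6 genes in Grin2a +/-, Grin2a -/- and Grin2b +/-.

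The library in no group, whose title and tissue label disagree, had Prkcd, a kinase of thalamic relay neurons, at 927.2 CPM. The 14 libraries of TH of that line at 2 weeks had 283 to 1354.1 CPM and the 14 of ST 9.2 to 12.8. Its Tcf7l2 was at 481 CPM and its Drd1 at 0.8 CPM, against 49.5 to 241.4 in ST.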

How the results depend on the processing

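The fits against marks-matched WT, without 5 outlying libraries and, in the Grin2b line, without the 20-week libraries were chosen after the data were seen. Over all alternatives, the counts and the targeted-gene values gave 278 values, of which 144 kept their direction and lay within 1.5 times the count first given. Of the others 132 lay beyond it, 2 lost their call or, for a targeted gene, an unadjusted p under 0.05, and 0 reversed. RLE factors moved none of them by that much. For the 184 called values of named genes, 2615 of 3051 alternative values kept their direction and their call, 436 kept the direction and lost the call, and 0 reversed, and 55 values of genes not called at first became called. Except where a sentence gives one, the cause was not tested.

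Genes called on average over the ages were 1038 in Grin2a +/-, 1066 in Grin2a -/-, 96 in libraries labelled Grin2b +/- and 2560 between Grin2a -/- and Grin2a +/-. DESeq2 gave 1588, 1704 and 491 for the first 3, and no filter on low counts 516 and 650 for the first 2. In Grin2b +/- limma-voom gave 63, a filter at a mean of 5 CPM 169 and a choroid plexus score as a covariate 40. With WT samples 1 to 5 alone in the groups of 10 the counts were 3009 in Grin2a +/-, 9476 in Grin2a -/- and 5229 between them, and with WT samples 6 to 10 alone 4501, 2076 and 4607. Marks-matched WT gave 502 in Grin2a +/- and 120 between the genotypes, and leaving out the 20-week libraries 2546 in Grin2a +/- and 1 in Grin2b +/-. Without 1 replicate number the ranges were 111 to 804, 404 to 1031, 2 to 737 and 970 to 1905, with fewer libraries in most groups.

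Calls at single ages were 6435, 10430 and 3603 in Grin2a +/-, Grin2a -/- and Grin2b +/-. Each region and age comparison fitted alone gave 2096, 665 and 239, with fewer libraries behind each estimate of spread. No filter on low counts gave 3771 and 6371 in the Grin2a line, and marks-matched WT 1731 and 3889. WT samples 6 to 10 alone gave 25733 in Grin2a +/-, WT samples 1 to 5 alone 31316 in Grin2a -/-, and leaving out the 20-week libraries, 1 of 4 ages, 3612 in Grin2a -/- and 1732 in Grin2b +/-. In Grin2b +/- DESeq2 gave 5801 and leaving out the 5 outlying libraries 5990. Without 1 replicate number the ranges were 2602 to 6112, 3104 to 6784 and 382 to 8366.

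Differences between ages were called for 982, 1753 and 336 genes in the same order. DESeq2 gave 2324, 3420 and 2235 and no filter on low counts 448, 853 and 166. Marks-matched WT gave 363 and 167 in the Grin2a line, leaving out the 20-week libraries 244 and 1137 (1 in Grin2b +/-), the choroid plexus score 137 and 1021, and WT samples 1 to 5 alone 2066 and 15526, while WT samples 6 to 10 alone gave 11368 in Grin2a +/-. In Grin2b +/- limma-voom gave 627, the filter at 5 CPM 889 and leaving out the outlying libraries 1217. Without 1 replicate number the ranges were 2 to 786, 83 to 1407 and 1 to 3861.

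Differences between regions were called for 310, 320 and 6 genes. Limma-voom gave 95 in Grin2a +/- and 1 in Grin2b +/-, and no filter on low counts 191, 196 and 1. WT samples 1 to 5 alone gave 1630 and 1605 in the Grin2a line and leaving out the 20-week libraries 1589 and 872 (22 in Grin2b +/-). Leaving out the outlying libraries gave 160 in Grin2a +/- and 10 in Grin2b +/-. Without 1 replicate number the ranges were 0 to 534, 25 to 547 and 0 to 17. Camera called 64, 67 and 71 pairs of region and list with the preset correlation and 0, 1 and 4 with an estimated one, and fry, which does not rank a list against other genes, gave 2, 16 and 6. The mean log2 difference of the targeted gene stayed between -0.57 and -0.53 in Grin2a +/-, between -1.54 and -1.48 in Grin2a -/- and between 0.055 and 0.131 in Grin2b +/- without 1 replicate number. In Grin2b +/- its unadjusted p was no longer under 0.05 without number 1 (log2 difference 0.055) and number 2 (0.09).

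Replicate numbers do not pair the genotypes: deviations of libraries with the same number, region and age had a mean r of -0.001 for Grin2a +/- and WT, 0.001 for Grin2a -/- and WT and 0.029 for Grin2b +/- and WT, and every pair exceeded 0.1 in 0, 0 and 1 of 20 group pairs. With the replicate number as a block within age, counts on average over the ages were 3131, 9293 and 61, and 5401 between the Grin2a genotypes. Single ages gave 30449 in Grin2a -/- and differences between ages 2041, 14637 and 866. The block leaves WT samples 6 to 10 without partners, so in the Grin2a line it compares much as WT samples 1 to 5 alone do. A replicate block over regions in limma-voom gave 746 region differences in Grin2a -/-.

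A covariate for sex was not run, since all libraries had the Y-linked transcript and almost no Xist. Fitting each comparison alone gives no mean over ages. At 9.47 M to 98.62 M counts a library, single ages are more limited than the mean over ages: on simulated SSC counts of Grin2a -/-, 65.7% of genes changed by 0.5 were recovered at 4 weeks and 88% on average.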

Other observations

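The counts of splits below used labels redrawn at random, and the real labels count as 1 of the 100 splits and 1 of those as large. Those for libraries labelled Grin2b +/- and, for marks-matched WT, those of differences between ages, of differences between regions and of lists were chosen after the results were seen, as were the outlying libraries.

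In HP of Grin2a -/-, 11 tested genes of hypothalamic nuclei and neuropeptides had a median log2 difference of 0.25 against WT, 10 of 11 positive. Crh and Pomc, precursors of stress-axis peptides, rose by 0.70 ± 0.136 and 0.69 ± 0.179 (edgeR adjusted p = 0.00176 and 0.0401; 18 and 13 of 19 libraries above the WT median), and 4 were higher adjusted over the list alone (camera adjusted p = 0.2 with an estimated correlation). Their levels were low, at 1.89 and 1.18 CPM. Without sample number 4 Pomc differed by 0.30 and without number 5 Crh by 0.62, and neither was then called. In Grin2a +/- they differed by 0.41 ± 0.136 and 0.39 ± 0.177 and were not called. Of 38 presynaptic genes over the 5 regions of Grin2a -/-, 4 calls were higher and 3 lower, or 13 and 16 adjusted over the list alone.

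In ST at 4 weeks of libraries labelled Grin2b +/- the genes with the smallest p were Vip, Lypd6b and Ddr2. Vip, a peptide of cortical interneurons, rose by 3.58 ± 0.562, Lypd6b by 2.44 ± 0.371 and Ddr2, a collagen receptor, by 0.93 ± 0.146 (edgeR adjusted p = 0.00115 each; 5 of 5 libraries above the WT median). Without sample number 3 none of them was called (3.62, 2.43 and 0.94). WT libraries averaged 0.311 CPM of Vip in ST and 44.9 in PFC. Over the ages, microglial genes had 16 higher calls and cytosolic ribosomal proteins 28 in this line when adjusted over the list alone, with 0 over all genes (smallest adjusted p = 0.24 and 0.46 with an estimated correlation).

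Outlying libraries by their distance from the group median (root mean square of log2 deviations, limit 0.461) were 5. WT sample 4 of HP at 2 weeks in the Grin2b line (0.936) had thalamic markers at a mean of 8.16 log2 CPM against 5.12 in the other WT samples. WT sample 4 of TH at the same age (0.597) had hippocampal markers at 5.45 against 3.29. Each thus carried markers of the other's region, the pattern an exchange of the 2 would give, and both were kept as labelled. Without the 5 outlying libraries 102 genes in place of 96 were called on average over the ages in libraries labelled Grin2b +/-, and 5990 in place of 3603 at single ages. Sample 3 labelled Grin2b +/- of ST at 20 weeks (0.643) had a total of 9.47 M counts. The others were Grin2a +/- sample 3 of TH at 20 weeks (0.565), with choroid plexus markers at 4.73 against 2.16, and WT sample 9 of ST at 20 weeks in the Grin2a line (0.531). Libraries with 1 number in different regions, of the same age and genotype, deviated together with a mean r of 0.214 over genes in the Grin2a line and 0.081 in the Grin2b line.

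Other splits of the libraries tested whether chance could give each count, with 100 splits each. Labels were redrawn without regard to the technical marks. For all WT libraries and for Grin2a -/- against Grin2a +/- these splits thus bear on chance and not on the library sets that line up with genotype. Shares of splits were not adjusted over the counts tested. A share of 1 in 100, the real labels alone, is the smallest possible, so it makes chance unlikely and does not exclude it. For Grin2a -/- against WT chance is unlikely for the mean over ages (1091 genes, 1 split as large, highest other 14) and single ages (10424, 1, highest other 9414). The same holds for differences between ages (1794, 1, highest other 1223) and between regions (275, 1, highest other 32). Chance cannot be excluded for the lists (65 pairs of region and list, 34 splits as large, highest other 86). For Grin2a +/- it is unlikely for the mean over ages (1128, 1, highest other 335), single ages (6428, 1, highest other 5868) and differences between ages (1163, 1, highest other 780). For differences between regions (76, 3, highest other 97) chance is made less likely and not excluded, and for the lists (60, 44, highest other 79) chance cannot be excluded. For Grin2a -/- against Grin2a +/- chance is unlikely for the mean over ages (2582, 1, highest other 140).

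Against marks-matched WT chance is unlikely and not excluded for the mean over ages in Grin2a -/- (819 genes, 1 split as large, highest other 753) and in Grin2a +/- (883, 1, highest other 170). The same holds for differences between regions in Grin2a -/- (185, 1, highest other 82) and in Grin2a +/- (130, 1, highest other 128). In the first and the last of these the highest other split lay close to the real count. Chance cannot be excluded for single ages in Grin2a -/- (3853, 5, highest other 4576) or Grin2a +/- (2467, 8, highest other 11430), for differences between ages (115, 18, highest other 2224, and 630, 7, highest other 3518) or for lists (71, 16, highest other 83, and 63, 47, highest other 84). For libraries labelled Grin2b +/- a share of 4 in 100 makes chance less likely for the mean over ages and does not exclude it (50 genes, highest other 1296). Chance cannot be excluded for single ages (3674, 9, highest other 6526), differences between ages (500, 5, highest other 2938), differences between regions (3, 13, highest other 139) or lists (70, 12, highest other 81). Splits that call several times the real count point to a structure of the samples.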
